A study of Mus musculus with 50 samples.

How the data were processed

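RNA was measured in biopsies of 50 separate mammary tumours, 1 array each, and their number limits the precision. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was made from 6 ug. The deposited values are log2 expression after RMA, which the authors ran (background correction, quantile normalization and median polish over the probes of a set), given to 2 decimals for 34472 probe sets. The version of RMA is not given in the sources used here, and the submitters' processing notes name the mouse build mm8 without its role. Quantile normalization makes the distributions of arrays alike, so a change shared by most genes would not be seen, and values near the bottom of the scale are compressed. The values carried no control probe sets by name, so the ratio of 3' to 5' signal was not computed.

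The platform annotation pairs 23521 probe sets with 1 gene, 1814 with several and 9137 with none, and no gene is named from probe sets with several. Of the Entrez identifiers, 23328 probe sets matched the gene table and 193 did not. Where a gene had several probe sets (1082 of 22180 genes) the one with the highest mean was used. Genes with a mean under 4.09 log2, the 25th percentile, were left out, which leaves 18045. Gene order along chromosomes came from a RefSeq table on the assembly GRCm38.p6, used only for names and order, and placed 17994 tested genes.

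All 50 samples formed 1 group. Before the data were examined, 36 gene lists were fixed, 34 of them for biology and the others for sex and for strain differences, together with the tests and alternatives. The spread of a list (median SD) and its mean pairwise r were set against 10000 random lists matched on mean expression in 20 bins, one-sided, for lists with at least 5 tested members. A list score is the mean of its genes standardised over tumours. Scores, single genes and array quality were correlated with two-sided permutation tests (100000 permutations). Regressions used limma 3.58.1 (lmFit and eBayes with trend) on Erbb2, the proliferation score and the T and NK cell score, each standardised over the tumours used and standardised again when arrays were left out, and camera with a correlation of 0.01 or an estimated one. Genes in a predictor were left out of its own counts. Genes with 2 levels were sought with mclust 6.1.1, as a BIC difference over 10 between 2 and 1 normal components of equal variance. All p values were adjusted by Benjamini-Hochberg and called under 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.

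Named genes followed a fixed rule: the 20 with the largest SD, in each regression the 10 with the largest positive and the 10 with the largest negative moderated statistic among called genes that kept their sign without the 2 tumours farthest from the predictor's median, in each list the 3 members with the largest statistic, all members of the drug lists, and the 20 with the largest BIC difference. Genes and tumours named outside these sets, such as list members given for their level, were chosen after their values were seen.

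Chromosome scores (mean standardised value of a chromosome's genes minus the median over chromosomes) and shifts (medians over genes above the 50th percentile of expression) were chosen after seeing the data. So were the runs without the 3 arrays whose mean correlation was under 0.96. For genes with 2 levels, 5 random choices of 3 other arrays were left out as a control, also chosen after. Alternatives were no filter, a filter at the 50th percentile, the mean of all probe sets, the probe set with the largest SD, another quantile normalization, ranks, array weights, covariates for 4 cell types, the median absolute deviation, Spearman's rho, medians as scores, arrays or tumours left out, stricter mixtures, and for neighbours the removal of 5 principal components or of pairs with related symbols.

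The tests were tested on simulated data. The limma regression recovered 86% of 100 planted genes at a slope of 0.2 and 98% at 0.5, with 14 false calls among 18045 genes. The mixture recovered 3% of 100 genes with a gap of 3 SD and 96% with 5 SD, with 0 false calls. The test of lists that move together recovered 3 of 3 planted lists with 2 false calls, and the neighbour test gave a mean r of 0.397 for 0.4 planted. The chromosome score recovered 1 of 1 chromosome planted with a shared change, with 0 false calls. There the mean r of genes more than 100 apart was 0.176 for a planted r of 0.2. The shifts on the log2 scale were not simulated. The correlation test recovered 100 of 100 pairs at r = 0.6 and called 3 of 100 without a relation. Tumours were not split by any measured value, and response to treatment was not analysed here.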

Results

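The data are 50 Affymetrix gene expression arrays, each from a biopsy of a separate mammary tumour taken before drug treatment. The tumours arose in female mice that carry the MMTV-ErbB2 transgene, in which the promoter of mouse mammary tumour virus drives the ErbB2 receptor tyrosine kinase in mammary epithelium. The mice came from a backcross of C57BL/6J x FVB/NJ hybrids to FVB/NJ mice with the transgene, so the mice differ in the chromosome segments they inherited. The labels put all 50 tumours in 1 group and give neither a response to treatment nor a batch, so the levels of genes, their spread between tumours and relations over the tumours are described. The labels differ on the drug that followed, with doxorubicin in the series title and docetaxel in the sample descriptions, so gene lists for both drugs were measured. Tumours are called by the names in their titles, such as mid60.

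Values lay between 2.53 and 13.65 on the log2 scale and the same quantile differed between arrays by a median of 0.12 and at most 0.35. The 2 most similar arrays correlated at r = 0.992, and 0 pairs of arrays were identical. The mean correlation of an array with the other arrays had a median of 0.978. It was under 0.96 in 3 arrays, mid79 at 0.916, mid60 at 0.931 and mid100 at 0.954. Xist, the RNA that silences an X chromosome in females, averaged 11.42 ± 0.22 log2 (SD, n = 50), while the Y-linked genes Kdm5d and Uty averaged 3.64 ± 0.11 and 3.44 ± 0.09. Among 4 genes known to differ between inbred strains, Nnt, the mitochondrial transhydrogenase, averaged 8.47 ± 0.31, Glo1, a glyoxalase, 8.30 ± 0.18, Hc, complement component C5, 4.27 ± 0.21, and Pde6b, a phosphodiesterase of rod cells, 3.84 ± 0.12.

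Erbb2 was among the high signals in most biopsies, with a mean of 11.58 ± 0.54 log2 (SD, n = 50) and a median of 11.71. The 5th and 95th percentiles, 11.13 and 11.92, lay 1.73-fold apart. Only mid60 at 9.02 and mid79 at 9.25 fell far below that range. Erbb3, the kinase-impaired partner of ErbB2, averaged 10.60 ± 0.60 with its lowest value, 6.88, in mid79, and Egfr averaged 8.94 ± 0.33. Erbb4 varied most among the receptors, at 7.31 ± 1.23 and 14.7-fold between the 5th and 95th percentiles. Among the ligands, Nrg1, a neuregulin that binds Erbb3 and Erbb4, averaged 6.41 ± 1.03, Nrg2 7.89 ± 0.51, Tgfa 7.14 ± 0.43 and Hbegf 7.01 ± 0.51. The 14 tested receptors and ligands had a median SD of 0.47, against 0.24 in random lists matched on expression (adjusted p = 0.00122), and did not move together (mean pairwise r = 0.0152, adjusted p = 0.308). The call on their spread held under 3 of 6 alternative settings and ended without mid79 and mid60 (median SD 0.29, adjusted p = 0.0694). Whether the Erbb2 probe set reads the transgene, the mouse gene or both is not given in the sources used here.

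**Figure D1:**
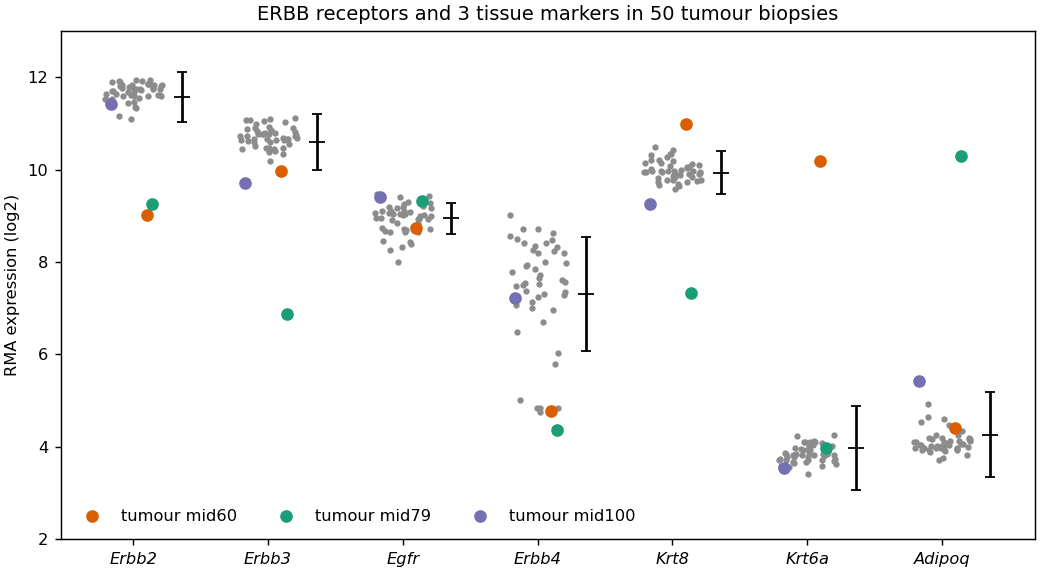
Levels (log2, vertical axis) of Erbb2, Erbb3, Egfr, Erbb4, Krt8, Krt6a and Adipoq in the 50 tumours, 1 point per tumour, with bars for the mean and SD and colours for mid60, mid79 and mid100. Erbb2 averages 11.58 with mid60 at 9.02 and mid79 at 9.25, while Krt6a is highest in mid60 and Adipoq in mid79.

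Most genes differed little between tumours. The median SD of 18045 tested genes was 0.23 log2, 4293 genes (23.8%) differed at least 2-fold between the 5th and 95th percentiles, and 839 (4.65%) at least 4-fold. The gene with the largest SD was Tfap2b, the transcription factor AP-2 beta, at 6.62 ± 2.54 log2 (SD, n = 50) with these percentiles at 3.77 and 9.72. The lower one is under 4.09, the lower limit for the mean of a tested gene, so their difference is a lower bound. Scgb1b27 and Scgb2b27, which code for secretoglobins, averaged 8.05 ± 2.50 and 10.30 ± 1.87 and were highest in mid130. Prol1, a proline-rich secreted protein, averaged 6.87 ± 1.95 and was also highest in mid130. The parotid-type genes Dcpp1 and Dcpp2 averaged 7.07 ± 1.78 and 6.65 ± 1.84, Fetub, a fetuin, 8.64 ± 1.90, and Apod, a lipocalin, 7.16 ± 1.83.

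Genes of the matrix were also in this set. Dcn, the proteoglycan decorin, averaged 7.99 ± 2.03, Dpt, dermatopontin, 6.95 ± 1.87, and Cnmd, chondromodulin, 7.76 ± 2.01 (SD, n = 50). Car3, a carbonic anhydrase of fat and muscle, averaged 6.83 ± 2.21 and, like Dcn and Dpt, was highest in mid79. Of genes active in lactation, Btn1a1, the butyrophilin of milk fat globules, averaged 8.72 ± 1.68 and Lao1, an amino acid oxidase found in milk, 6.84 ± 1.87. The interferon-inducible genes Ifi205 and Apol9b averaged 7.23 ± 1.79 and 6.76 ± 1.74. The cation channel Trpm3 averaged 7.17 ± 1.75, the GABA receptor subunit Gabra4 4.57 ± 1.66, the potassium channel partner Dpp10 6.86 ± 1.83, and Emb, embigin, 8.55 ± 1.92.

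Of 33 fixed gene lists with at least 5 tested members, 26 were more variable between tumours than random lists matched on expression (16 by the median absolute deviation), and the members of 29 moved together, with adjusted p values of at most 0.0479 and 0.0149. Over all 50 tumours milk protein genes had the highest median SD, 1.17 log2 over 12 members (p = 0.0001, the smallest the random lists can give, adjusted p = 0.000236), with a mean pairwise r of 0.328. The caseins Csn2 and Csn1s1 averaged 12.01 ± 1.52 and 11.11 ± 1.58 (SD, n = 50) and were lowest in mid99, at 4.82 and 4.52, while Wap, the whey acidic protein, averaged 5.43 ± 0.41. The 10 lists that lost the call on spread by the median absolute deviation were those for ERBB receptors and ligands (adjusted p = 0.137), adipocytes (0.243), muscle (0.858), T and NK cells (0.256), B cells (0.502), neutrophils (0.201), peripheral nerve (0.201), skin (0.89), the unfolded protein response (0.137) and cholesterol synthesis (0.137). The 19 luminal genes had a median SD of 0.55 (r = 0.288), or 0.34 (r = 0.0813) without mid79 and mid60, the 11 basal and myoepithelial genes 0.50 (r = 0.316) and the 33 proliferation genes 0.52 (r = 0.792). Krt8, a keratin of simple epithelium, averaged 9.94 ± 0.46, Esr1, the oestrogen receptor, 6.83 ± 0.50, and Mki67, a marker of cycling cells, 9.98 ± 0.56. Members of lists named here for their level were chosen after their values were seen.

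Lists of tissues around the epithelium varied widely. The 22 fibroblast and matrix genes had a median SD of 1.04 log2 and a mean r of 0.856, the 18 endothelial genes 0.62 and 0.801, the 14 adipocyte genes 0.97 and 0.727, and the 15 skeletal muscle genes 1.04 and 0.914 (0.392 by Spearman's rho). Without mid79 and mid60 the adipocyte values were 0.41 and 0.522, and without mid100 as well 0.30 and 0.418, with a median SD of 0.39 for endothelium. Muscle genes were high in few biopsies, with scores of 4.71 in mid100 and 4.19 in mid71 (a score is a mean of standardised genes). The adipocyte score was 5.32 in mid79 and 1.57 in mid100, which came next. The 14 skin and squamous genes (median SD 0.73, r = 0.829) scored 6.29 in mid60 and 0.24 in mid65, which came next, and their calls on spread and on moving together held under 3 and 4 of 6 alternatives. Without mid79 and mid60 their values were 0.18 and 0.0543 (adjusted p = 0.447 and 0.113). The 6 peripheral nerve genes varied (median SD 0.62, adjusted p = 0.0033) without moving together (mean r = 0.0317, adjusted p = 0.316), and without the 3 arrays their median SD was 0.38. Of the red blood cell list 1 gene was measured, the anion exchanger Slc4a1 at 5.20 ± 0.24 (SD, n = 50), so that list was not tested.

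Immune lists differed in how far they varied. The 21 interferon response genes had a median SD of 0.92 log2 and a mean r of 0.812, with Oas2, an antiviral synthetase, at 7.51 ± 1.36 and Ifit1 at 7.82 ± 1.35 (SD, n = 50). The 9 genes of MHC class I presentation had 0.75 and 0.773, the 18 macrophage genes 0.60 and 0.654, the 8 neutrophil genes 0.46 and 0.556 (0.208 by Spearman's rho), and the 11 B and plasma cell genes 0.43 and 0.664. The 18 T and NK cell genes moved together (r = 0.362) with a median SD of 0.25 (adjusted p = 0.0479), a call on spread that held under 2 of 6 alternatives, while that of the B cell list held under 3 of 6. Without mid79 and mid60 the B cell values were 0.18 and 0.101 (adjusted p = 0.368 and 0.012) and those of T and NK cells 0.19 and 0.233 (adjusted p = 0.254 and 0.00015). The 7 genes of MHC class II presentation moved together (r = 0.30) but were not more variable than matched genes (median SD 0.31, adjusted p = 0.164).

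Among lists of cell state, the 20 hypoxia genes had a median SD of 0.58 log2 (r = 0.377), with the hormone precursor Adm at 7.0 ± 0.95 (SD, n = 50) and the carbonic anhydrase Car9 at 7.44 ± 0.94. The 13 genes of epithelial to mesenchymal transition had 0.58 (r = 0.470), the 13 immediate early genes 0.52 (r = 0.218), the 11 Wnt targets 0.50 (r = 0.267), the 9 genes of fatty acid synthesis 0.48 (r = 0.249) and the 9 of cholesterol synthesis 0.47 (r = 0.489). The 19 p53 targets had 0.35 (adjusted p = 0.0169, r = 0.195) and the 16 genes of the unfolded protein response 0.34 (adjusted p = 0.0426, r = 0.378). The call that Wnt targets move together held under 3 of 6 alternatives, and without mid79 and mid60 their values were 0.28 and -0.0214 (adjusted p = 0.063 and 0.827). Some lists were no more variable than matched genes although their members moved together, namely 20 genes of double-strand break repair (median SD 0.30, adjusted p = 0.170, r = 0.251), 10 heat shock genes (0.23, adjusted p = 0.827, r = 0.195), 19 genes of oxidative phosphorylation (0.20, adjusted p = 0.985, r = 0.215) and 17 ribosomal protein genes (0.20, adjusted p = 0.985, r = 0.275).

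**Figure D2:**
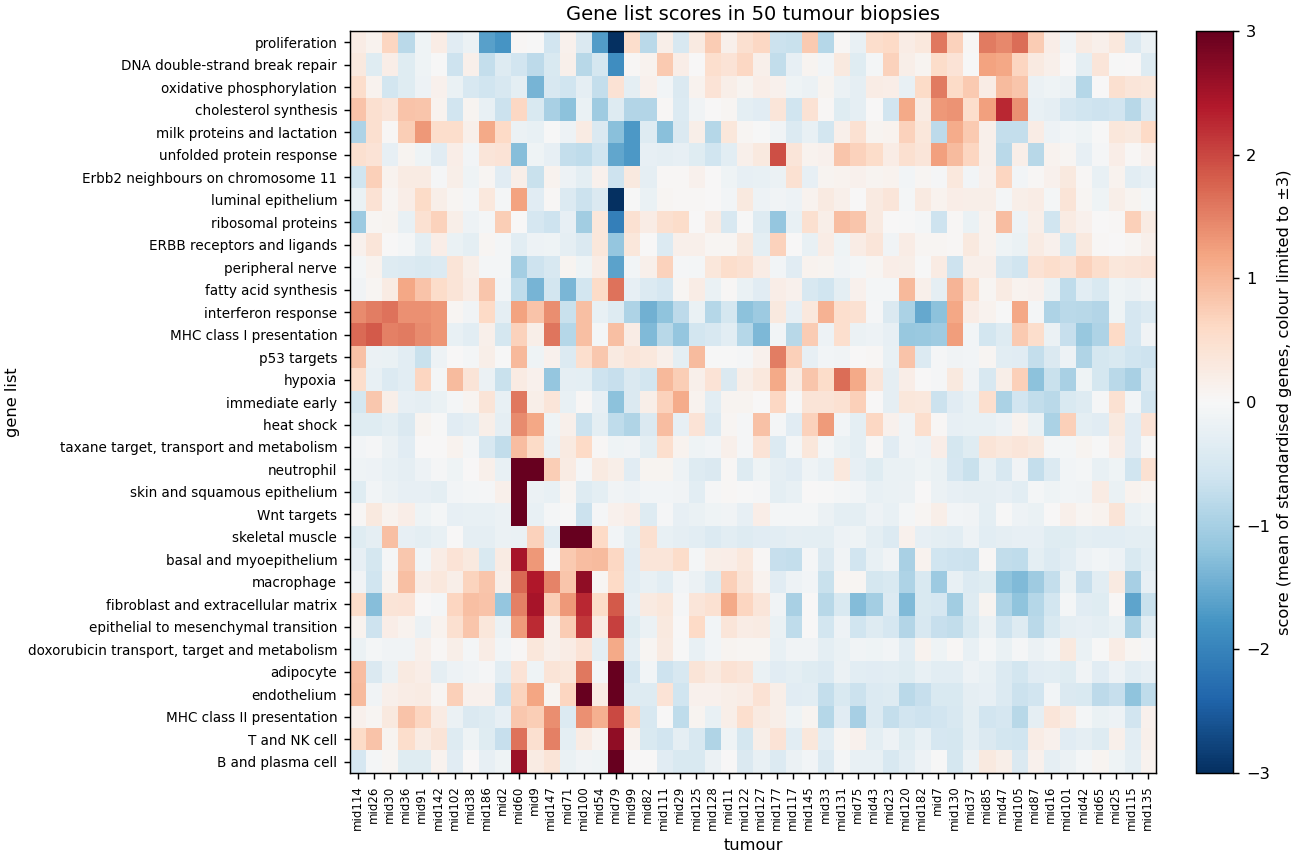
Heat map of the scores of 33 gene lists (vertical axis) in the 50 tumours (horizontal axis), where a score is the mean over members of each gene standardised over tumours and colours are limited to 3 SD units either way. The skin score of 6.29 in mid60, the adipocyte score of 5.32 in mid79 and the muscle scores of 4.71 in mid100 and 4.19 in mid71 stand apart.

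The doxorubicin list holds transporters, targets and metabolic enzymes of the drug. Its 27 tested genes were not more variable than matched genes (median SD 0.28 log2, adjusted p = 0.101) and did not move together (mean r = 0.0206, adjusted p = 0.308). Top2a, the topoisomerase that doxorubicin poisons, averaged 8.31 ± 0.62 (SD, n = 50) and differed 3.85-fold between the 5th and 95th percentiles, while Top2b was steadier at 8.50 ± 0.16. The efflux pump gene Abcb1a averaged 5.48 ± 0.42 with its highest value, 7.27, in mid100, and Abcb1b 4.55 ± 0.47 with its highest, 7.08, in mid79. Abcg2, another efflux pump, differed 5.47-fold (8.02 ± 0.78) and Abcc1 averaged 7.68 ± 0.40. Of redox enzymes, Hmox1, haem oxygenase, differed 14.2-fold (9.17 ± 1.15) and Nqo1, a quinone reductase, 5.69-fold (7.17 ± 0.81).

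The taxane list holds tubulins, tubulin-binding proteins and enzymes for docetaxel. Its 21 tested genes were more variable than matched genes (median SD 0.42 log2, adjusted p = 0.000236) and moved together weakly (mean r = 0.0535, adjusted p = 0.0149). Tubb5, a main beta-tubulin, averaged 11.13 ± 0.28 (SD, n = 50), Tubb6 7.87 ± 0.54 and Tuba1a 6.33 ± 0.54. Cyp1b1, a cytochrome P450 that acts on docetaxel, differed 8.52-fold between the 5th and 95th percentiles (5.58 ± 0.89), while Cyp3a11, of the liver family that clears taxanes, stayed at 4.10 ± 0.16. Microtubule-associated Map2 averaged 8.54 ± 0.48, Map4 7.35 ± 0.42 and Mapt 4.70 ± 0.13, and Bcl2, an inhibitor of apoptosis, 9.22 ± 0.53.

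Relations between list scores were computed for 28 planned pairs over the 50 tumours, with permutation p values whose smallest possible value is 1e-05. By Pearson's r 20 pairs passed, by Spearman's rho 13, and by r without the 2 tumours farthest from the median of the first score 14. Proliferation rose with double-strand break repair, with r = 0.791 and rho = 0.718 (each p = 1e-05, adjusted p = 4.67e-05) and r = 0.720 without mid79 and mid2. Top2a rose with the proliferation score, with r = 0.964 and rho = 0.905 (each p = 1e-05, adjusted p = 4.67e-05) and r = 0.942 without the same 2 tumours. Stromal scores rose together. For macrophage and fibroblast genes r was 0.825 and rho 0.759 (each p = 1e-05, adjusted p = 4.67e-05), with r = 0.749 without mid100 and mid9. For endothelium and fibroblast genes r was 0.777 and rho 0.808 (each p = 1e-05, adjusted p = 4.67e-05), with r = 0.822 without mid79 and mid100. The basal and myoepithelial list is epithelial, but its score also rose with that of fibroblast genes. There r was 0.751 and rho 0.753 (each p = 1e-05, adjusted p = 4.67e-05), with r = 0.703 without mid9 and mid100. The basal list includes contractile genes such as Acta2 and Tagln, and which cells expressed them was not tested.

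T and NK cell genes rose with MHC class I genes, with r = 0.583 (permutation p = 3e-05, adjusted p = 9.33e-05), rho = 0.609 (p = 1e-05, adjusted p = 4.67e-05) and r = 0.658 without mid79 and mid60. With interferon response genes r was 0.406 (p = 0.00237, adjusted p = 0.00519), rho 0.450 (p = 0.00129, adjusted p = 0.00401) and r without those 2 tumours 0.542. With macrophage genes r was 0.460 (p = 0.0018, adjusted p = 0.00504), rho 0.414 (p = 0.00291, adjusted p = 0.00815) and r without mid100 and mid9 0.503. The relation of T and NK cell to B cell genes was weaker without mid79 and mid60. Over all tumours r was 0.750 (p = 1e-05, adjusted p = 4.67e-05) but rho 0.304 (p = 0.0325, adjusted p = 0.0606), and r without those 2 tumours was 0.310 (p = 0.0321, adjusted p = 0.0562). The inverse relation of proliferation to T and NK cell genes passed by r over all tumours only. It gave r = -0.440 (p = 0.00405, adjusted p = 0.00756), rho = -0.242 (p = 0.0911, adjusted p = 0.134) and r = -0.242 without mid79 and mid2 (adjusted p = 0.144). By camera with the preset correlation the T and NK cell list was still lower with the proliferation score without mid79 and mid2 (adjusted p = 0.0186). It was not without mid60, mid79 and mid100 (adjusted p = 0.179), nor over all tumours with an estimated correlation (adjusted p = 0.307). By limma 0 of its 18 genes passed without mid79 and mid2, with 2 at an unadjusted p under 0.05.

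Abcb1a rose with endothelial genes, with r = 0.811 (permutation p = 2e-05, adjusted p = 7e-05), rho = 0.454 (p = 0.00104, adjusted p = 0.00364) and r = 0.389 without mid100 and mid79 (adjusted p = 0.0138). Abcb1b rose with endothelial genes, with r = 0.761 (p = 2e-05, adjusted p = 7e-05), rho = 0.380 (p = 0.00678, adjusted p = 0.0158) and r = 0.492 without mid79 and mid9, and with macrophage genes, with r = 0.479 (p = 0.00234, adjusted p = 0.00519), rho = 0.398 (p = 0.00454, adjusted p = 0.0116) and r = 0.542. Luminal genes rose with milk protein genes, with r = 0.366 (p = 0.0129, adjusted p = 0.0190), rho = 0.368 (p = 0.00905, adjusted p = 0.0195) and r = 0.330 without mid79 and mid60 (adjusted p = 0.0439). Against basal genes the luminal score gave r = -0.0937 (p = 0.472, adjusted p = 0.508), rho = -0.211 (p = 0.139, adjusted p = 0.186) and, without the same tumours, r = -0.425 (adjusted p = 0.00616). Erbb2 with proliferation gave r = 0.416 (p = 0.0109, adjusted p = 0.0169), but rho was 0.20 (p = 0.165, adjusted p = 0.210) and r without mid60 and mid79 0.227 (adjusted p = 0.162). Camera still called the proliferation list higher with Erbb2 without them (adjusted p = 3.50e-05), while with an estimated correlation over all tumours it did not (adjusted p = 0.453).

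Over all 50 tumours the list of B cell genes fell with the level of Erbb2 (adjusted p = 0.0139 with an estimated correlation), but not without mid60 and mid79 (adjusted p = 0.919). Of 18045 tested genes other than Erbb2, limma called 2991 higher and 2658 lower where Erbb2 was higher. These calls rested on mid60 and mid79, since 82 genes passed without them, 59 of them shared. Etv1, an ETS transcription factor, rose by 0.66 ± 0.04 log2 per SD of Erbb2 (SE, n = 50, adjusted p = 5.97e-18), and without the 2 tumours its slope was 0.06 (adjusted p = 0.278). Slopes without the 2 tumours are per SD of Erbb2 over the remaining tumours, a smaller unit, so the sizes of slopes are not comparable between the 2 runs. Tfap2c, the transcription factor AP-2 gamma, rose by 0.64 ± 0.04, Col9a1, a collagen of cartilage, by 0.81 ± 0.05, and Foxi1, a forkhead factor, by 0.72 ± 0.05. Chrm3, a muscarinic receptor, rose by 0.94 ± 0.06, with a slope of 0.03 without the 2 tumours. Slc16a10, an amino acid transporter, had a slope of -0.47 ± 0.03 (adjusted p = 5.44e-18) and was still called without them (-0.13, adjusted p = 0.0274). Apcdd1, an inhibitor of Wnt signalling, had a slope of -0.82 ± 0.05, Ms4a1, the B cell antigen CD20, -0.64 ± 0.05, and Msln, mesothelin, -0.33 ± 0.03.

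By list, camera called 18 of 33 with the preset correlation, 5 higher and 13 lower with Erbb2, and 1 with an estimated correlation, the B and plasma cell list. Of its 11 genes 10 fell (10 adjusted over the list alone, median slope -0.35, adjusted p = 1.23e-14, and adjusted p = 0.0139 with an estimated correlation), among them Cd79a, a chain of the B cell receptor, with a slope of -0.63 ± 0.05 log2 per SD (SE, n = 50). Of 14 adipocyte genes 13 fell (13 adjusted over the list alone, median slope -0.57, adjusted p = 1.27e-10, and adjusted p = 0.128 with an estimated correlation), among them Lep, leptin, at -0.67 ± 0.10. All 14 skin genes fell (14 adjusted over the list alone, median slope -0.45, adjusted p = 1.30e-12, and adjusted p = 0.128 with an estimated correlation), with the keratin Krt10 at -0.52 ± 0.08. Of 18 endothelial genes 17 fell (17 adjusted over the list alone, median slope -0.30, adjusted p = 1.34e-10, and adjusted p = 0.205 with an estimated correlation), among them Pecam1 at -0.40 ± 0.08. Of 33 proliferation genes 23 rose (28 adjusted over the list alone, median slope 0.20, adjusted p = 5.30e-07, and adjusted p = 0.453 with an estimated correlation), with the kinase Cdk1 at 0.30 ± 0.07. Of 19 luminal genes 10 rose and 4 fell (11 and 4 adjusted over the list alone, median slope 0.21, adjusted p = 0.0237, and adjusted p = 0.55 with an estimated correlation), with Kit, a receptor kinase of luminal progenitors, at 0.70 ± 0.07 and Epcam, an epithelial adhesion molecule, at 0.37 ± 0.04.

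Without mid60 and mid79, 12 lists were called and 8 of them were among the 18. The lists for fibroblasts (adjusted p = 1.07e-08), endothelium (6.64e-10), macrophages (2.21e-08), the interferon response (1.07e-08) and hypoxia (3.28e-08) were lower and that for proliferation (3.50e-05) was higher in these 48 tumours. With an estimated correlation, run over all 50 tumours, their adjusted p values in the same order were 0.40, 0.205, 0.452, 0.685, 0.836 and 0.453. Tested singly by limma in the 48 tumours, 1 of the 20 hypoxia genes passed (10 at an unadjusted p under 0.05), and 0 in the other 5 lists, with 7, 11, 9, 10 and 8 at an unadjusted p under 0.05 for fibroblasts, endothelium, macrophages, interferon and proliferation. The B cell, skin, luminal and T and NK cell lists were no longer called, at adjusted p = 0.919, 0.919, 0.625 and 0.469. Over the 50 tumours the ERBB list, Erbb2 left out, and the list for oxidative phosphorylation were not called (adjusted p = 0.524 and 0.830) and their medians, -0.01 and -0.00052, had the opposite sign to camera's direction.

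The list of double-strand break repair rose with the proliferation score (adjusted p = 0.00556 with an estimated correlation). Outside the score's own members, limma called 1979 genes higher and 1435 lower. Top2a rose by 0.60 ± 0.02 log2 per SD of the score (SE, n = 50, adjusted p = 1.57e-25), Ect2, an exchange factor of cytokinesis, by 0.67 ± 0.03, Racgap1, its partner, by 0.47 ± 0.02, and Mad2l1, of the spindle checkpoint, by 0.44 ± 0.02. Without mid79 and mid2, 917 genes passed, 788 of them shared, and these 4 were among them, with slopes of 0.44, 0.44, 0.37 and 0.35. Slopes without the 2 tumours are per SD of the score over the remaining tumours, so their sizes are not comparable with those over all 50. Nek7, a kinase of the inflammasome, had a slope of -0.25 ± 0.03 (adjusted p = 1.81e-07, and -0.23 without the 2 tumours). Abca1, the cholesterol exporter, had -0.37 ± 0.06 (adjusted p = 6.81e-06, and -0.40 without them), Steap4, a metalloreductase, -0.63 ± 0.10 and Cyp4v3, a fatty acid hydroxylase, -0.50 ± 0.07. Fgf13 and Fbxo4 were no longer called without the 2 tumours, at adjusted p = 0.138 and 0.0603.

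Camera called 13 of 32 lists with this score, 3 higher and 10 lower, and 1 with an estimated correlation, double-strand break repair. There 12 of 20 genes rose (13 adjusted over the list alone, median slope 0.13, adjusted p = 5.06e-10, and adjusted p = 0.00556 with an estimated correlation), Fancd2, of the Fanconi pathway, by 0.32 ± 0.03 log2 per SD (SE, n = 50), Brca1 by 0.36 ± 0.03 and the checkpoint kinase Chek1 by 0.38 ± 0.03. Of 9 genes of cholesterol synthesis 5 rose (5 adjusted over the list alone, median slope 0.18, adjusted p = 0.00107, and adjusted p = 0.307 with an estimated correlation), with Sqle, squalene epoxidase, at 0.31 ± 0.06 and Fdps at 0.28 ± 0.06. Of 18 macrophage genes 6 fell (15 adjusted over the list alone, median slope -0.21, adjusted p = 4.73e-06, and adjusted p = 0.351 with an estimated correlation), with the receptor Csf1r at -0.24 ± 0.08. Of 14 adipocyte genes 11 fell (13 adjusted over the list alone, adjusted p = 1.79e-10, and adjusted p = 0.307 with an estimated correlation). By limma 0 adipocyte genes passed without mid79 and mid2 (1 at an unadjusted p under 0.05), against 4 macrophage, 5 cholesterol and 9 repair genes. Camera still called the adipocyte list there (adjusted p = 0.0244), but not without mid60, mid79 and mid100 (adjusted p = 0.217). Among drug genes, Tubb5 rose by 0.18 ± 0.03 and Stmn1, the microtubule destabiliser stathmin, by 0.21 ± 0.04. The doxorubicin and taxane lists as wholes were not called (adjusted p = 0.0885 and 0.158), but the taxane list was higher without mid60, mid79 and mid100 (adjusted p = 0.0242) and with cell-type covariates (adjusted p = 0.0054), against adjusted p = 0.454 with an estimated correlation over all 50. Not called either was the skin list (adjusted p = 0.579), whose median slope, 0.01, had the opposite sign to camera's direction. Without mid79 and mid2 16 lists were called, 11 of them among the 13, and the luminal list was not (adjusted p = 0.590).

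With the T and NK cell score, single genes of lymphocytes such as Ptpn22 and Il2rb rose, while camera called 0 of 32 lists with an estimated correlation (7 at an unadjusted p under 0.05). Outside the score's own members, limma called 2223 genes higher and 2778 lower. Ptpn22, a phosphatase of lymphocyte signalling, rose by 0.62 ± 0.05 log2 per SD of the score (SE, n = 50, adjusted p = 3.39e-14), Klrd1, the NK receptor CD94, by 0.29 ± 0.03, Il2rb, a chain of the IL-2 receptor, by 0.31 ± 0.03, Stat4 by 0.34 ± 0.03 and Cd274, the checkpoint ligand PD-L1, by 0.51 ± 0.05. Without mid79 and mid60, 513 genes passed, 458 of them shared, and those 5 were among them, with slopes of 0.41, 0.21, 0.26, 0.14 and 0.28. Here too, slopes without the 2 tumours are per SD of the score over the remaining tumours, so their sizes are not comparable with those over all 50. Ikzf3, a lymphoid factor encoded near Erbb2, rose by 0.38 ± 0.03. Papss1, an enzyme of sulphate activation, had a slope of -0.33 ± 0.04 (adjusted p = 5.13e-09, and -0.11 without the 2 tumours), Tmx1, a thioredoxin of the endoplasmic reticulum, -0.22 ± 0.03 and Wdr77 -0.20 ± 0.03. Col9a1, Srgap3 and Tom1l1 were no longer called without the 2 tumours, at adjusted p = 0.202, 0.203 and 0.20.

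Camera called 18 of 32 lists with this score, 13 higher and 5 lower, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. Of 9 genes of MHC class I presentation 8 rose (9 adjusted over the list alone, median slope 0.40, adjusted p = 2.10e-07, and adjusted p = 0.172 with an estimated correlation), with Nlrc5, their transactivator, at 0.66 ± 0.11 log2 per SD and B2m at 0.29 ± 0.06 (SE, n = 50). Of 7 genes of MHC class II presentation 6 rose (6 adjusted over the list alone, median slope 0.23, adjusted p = 4.97e-05, and adjusted p = 0.0523 with an estimated correlation), among them Ciita at 0.18 ± 0.03. Of 21 interferon response genes 14 rose (15 adjusted over the list alone, median slope 0.30, adjusted p = 2.10e-07, and adjusted p = 0.30 with an estimated correlation), with Oas2 at 0.69 ± 0.16. Of 18 macrophage genes 14 rose (16 adjusted over the list alone, median slope 0.24, adjusted p = 4.91e-07, and adjusted p = 0.271 with an estimated correlation), with the adaptor Tyrobp at 0.34 ± 0.07. Of 33 proliferation genes 25 fell (28 adjusted over the list alone, median slope -0.20, adjusted p = 6.89e-09, and adjusted p = 0.316 with an estimated correlation), with the thymidylate synthase Tyms at -0.20 ± 0.04. By limma 0 of them passed without mid79 and mid60 (8 at an unadjusted p under 0.05), while camera still called the list lower (adjusted p = 0.0031, and 0.00267 without mid100 as well). With cell-type scores as covariates it was not called (adjusted p = 0.994). Of 20 genes of double-strand break repair 13 fell (13 adjusted over the list alone, median slope -0.11, adjusted p = 3.41e-05, and adjusted p = 0.172 with an estimated correlation), with Xrcc6 at -0.16 ± 0.03, and 3 passed without the 2 tumours, where camera still called the list (adjusted p = 4.46e-05). In the same run 8 genes of MHC class I, 4 of class II, 18 of the interferon response and 6 of macrophages passed. Without mid79 and mid60 13 lists were called, 12 of them among the 18, and the B cell list was not (adjusted p = 0.0663). Camera's direction and the median slope differed in sign for 2 lists that were not called, heat shock (median -0.02, adjusted p = 0.859) and taxane (median -0.01, adjusted p = 0.344).

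Genes next to Erbb2 on chromosome 11 were followed because neighbours are often amplified with it in human tumours. In these mice a transgene drives ErbB2, and whether the Erbb2 probe set reads it is not given, so the relations below do not decide on amplification. As a list, the 18 tested neighbours were neither more variable than matched genes (median SD 0.24 log2, adjusted p = 0.567) nor moved together (mean r = 0.0210, adjusted p = 0.258). Singly, 4 of 18 relations with Erbb2 passed over 50 tumours. Pgap3 gave r = 0.538 (permutation p = 0.00026, adjusted p = 0.00252) and rho = 0.121 (p = 0.402, adjusted p = 0.852), Mien1 r = 0.520 (p = 0.00028, adjusted p = 0.00252) and rho = 0.211 (p = 0.142, adjusted p = 0.625). The lipid transfer gene Stard3 gave r = 0.466 (p = 0.0049, adjusted p = 0.0221) and rho = 0.261 (p = 0.0668, adjusted p = 0.601), and Ikzf3 r = -0.748 (p = 0.0006, adjusted p = 0.0036) and rho = -0.0700 (p = 0.629, adjusted p = 0.922). The adaptor gene Grb7 did not pass (r = 0.498, p = 0.0208, adjusted p = 0.0747; rho = -0.0268, p = 0.852, adjusted p = 0.959; r = -0.0314 without mid60 and mid79). All 4 relations no longer passed without mid60 and mid79, where r was 0.149 for Pgap3, 0.111 for Mien1, 0.30 for Stard3 and -0.0193 for Ikzf3. By permutation 0 of the 18 passed there, 1 of them, Stard3, with an unadjusted p under 0.05 (p = 0.0383, adjusted p = 0.576).

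The mean correlation of an array with the others was set against the list scores. Both come from the same values, so a biopsy with unusual scores also correlates less with the others. The relations below therefore cannot tell array quality from tissue content. Of 33 relations 20 passed by Pearson's r, 17 without the 2 lowest arrays and 1 by Spearman's rho. B cell genes gave r = -0.896 (permutation p = 7e-05, adjusted p = 0.000528), rho = -0.0730 (p = 0.614, adjusted p = 0.699) and r = -0.0779 without mid79 and mid60, on which the relation rested. Adipocyte genes gave r = -0.792 (p = 0.00033, adjusted p = 0.00128), rho = -0.158 (p = 0.273, adjusted p = 0.429) and r = -0.535 without the same 2 arrays. Endothelial genes gave r = -0.742 (p = 0.00062, adjusted p = 0.00205), rho = -0.321 (p = 0.0231, adjusted p = 0.127) and r = -0.726 without the 2 arrays. Peripheral nerve genes, the list that passed by rho, gave r = 0.680 (p = 3e-05, adjusted p = 0.000528), rho = 0.499 (p = 0.00035, adjusted p = 0.0116) and r = 0.331 without them (adjusted p = 0.0394).

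Genes that lie next to each other on a chromosome moved together more than genes apart. The mean r of 17974 adjacent pairs was 0.129, against 0.00589 ± 0.00167 (SD) in 1000 shuffles of gene order, with p = 0.001, the smallest the shuffles can give (r here is between genes, which are not independent replicates). It was 0.0732 at 2 to 5 genes apart, 0.0560 at 6 to 20, 0.0495 at 21 to 100 and 0.0447 beyond 100, against 0.00355 for genes on different chromosomes. By chromosome the adjacent pairs of chromosome 4 were highest at 0.238, with chromosomes 18 at 0.224 and 12 at 0.187 next.

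**Figure D3:**
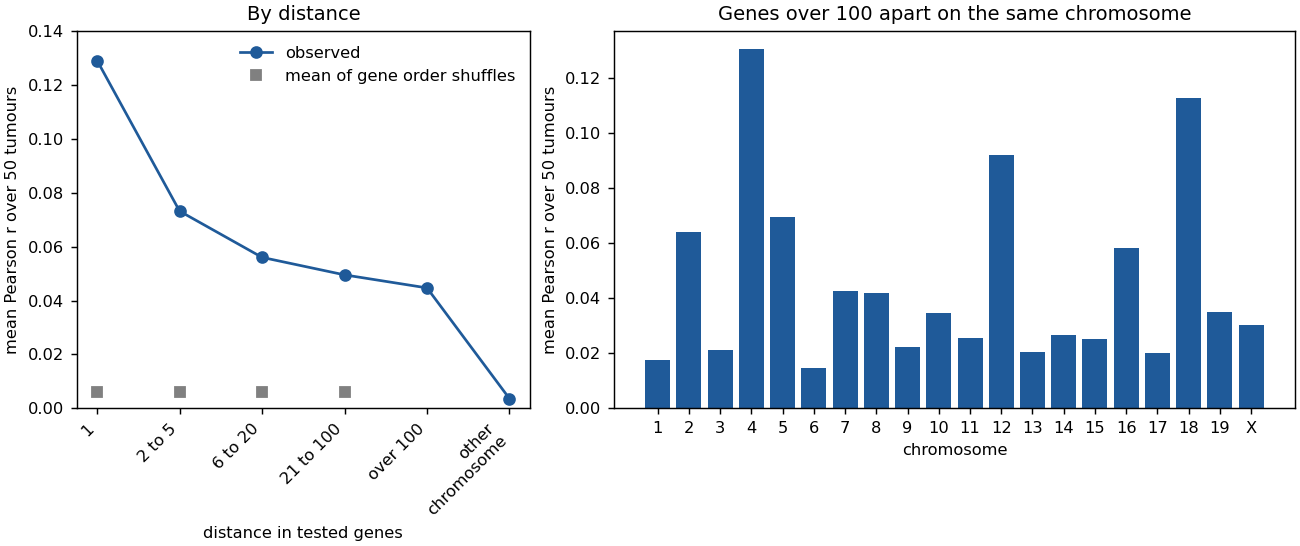
Mean r of gene pairs over the 50 tumours (vertical axes) by distance in gene order, beside shuffled gene order, and as bars for each chromosome over pairs more than 100 genes apart. The mean falls from 0.129 for adjacent pairs to 0.0447 beyond 100 genes, and reaches 0.131 on chromosome 4 and 0.113 on chromosome 18.

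Shared shifts of the genes of each chromosome were measured after this result was seen. The shift of a chromosome in a tumour is the median log2 deviation of its genes from their medians over the tumours, relative to the other chromosomes. The scores of all 20 chromosomes varied more than in any of 1000 shuffles of gene order, also without mid60, mid79 and mid100. The shuffles also break the correlation of near neighbours, so passing them does not by itself show a shift of a whole chromosome. On chromosomes 1, 9, 10, 13, 17 and X, 0 tumours shifted by more than 0.2 either way. Chromosome 4 varied most, with 84.8% of its 1080 genes in positive correlation with the rest of the chromosome. Its shifts ran from -0.21 in mid16 to 0.30 in mid87, with 12 tumours above 0.2 and 2 below -0.2. Others lay close to the lower limit, such as mid82 at -0.195 and mid145 at -0.19. The level 0 is set by medians over the tumours, so a rise in some cannot be told from a fall in others. Chromosome 18 reached 0.62 in mid11 with 5 tumours above 0.2, chromosome 12 reached 0.40 in mid125 with 7, and chromosome 5 reached 0.47 in mid177 with 3. Downward shifts reached -0.39 for chromosome 7 in mid111, -0.37 for chromosome 16 and -0.35 for chromosome 8 in mid125, and -0.33 for chromosome 19 in mid127. DNA measurements were not used here.

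**Figure D4:**
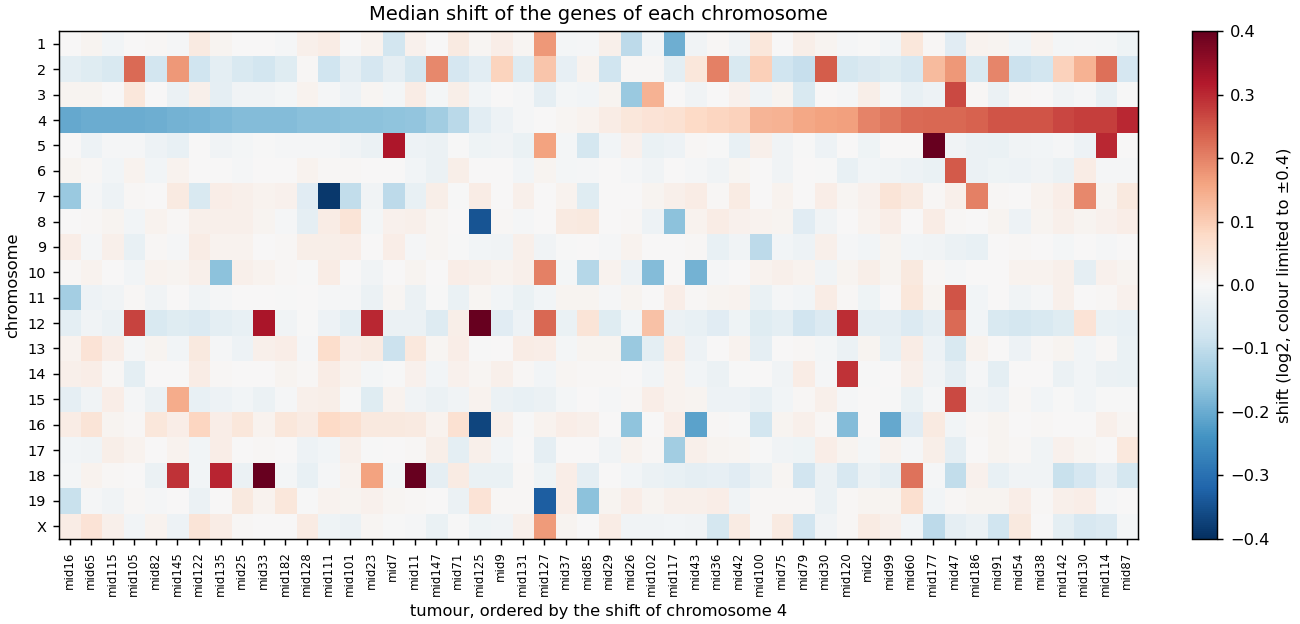
Heat map of the shift (log2) of 20 chromosomes (vertical axis) in the 50 tumours (horizontal axis, ordered by the shift of chromosome 4), with colours limited to 0.4 either way. Chromosome 4 runs from -0.21 to 0.30, and single tumours reach 0.62 on chromosome 18, 0.47 on chromosome 5 and -0.39 on chromosome 7.

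In a backcross each autosomal locus has 2 possible genotypes, so genes with 2 levels between tumours were sought with mixtures of normal distributions. Among the 20 genes with the largest BIC difference, Tfap2b had the most even split. The means of its fitted components lay 4.92 log2 apart with an SD of 0.54 within them, and 52% of the tumours were in the upper one (BIC difference 77.4, n = 50). This gap is a lower bound, since values near the bottom of the scale are compressed. In all, 1483 of 18045 genes were called, against 1 of as many simulated normal genes, and 477 without mid60, mid79 and mid100. The simulated genes each follow 1 normal distribution, so a skewed gene can also be called without having 2 levels. Most of the 20 genes with the largest BIC difference split off few tumours. Cnksr2, a scaffold protein of synapses, had 8% of tumours in its upper component (gap 1.77). Its mean, 4.115 log2, is close to the lower limit for tested genes, so this gap is also a lower bound. Glycam1, a mucin of milk, had 8% in the upper component (gap 3.93), Fst, follistatin, 6% (1.87) and Has2, hyaluronan synthase, 6% (3.08). Tfap2c, Foxi1, Socs2, a suppressor of cytokine signalling, and Acsl4, an acyl-CoA synthetase, had 96% in the upper component, with gaps of 3.31, 3.74, 3.77 and 2.99. Without mid60, mid79 and mid100 the call held for 4 of these 20 genes, Cnksr2 (BIC difference 79.1), Tfap2b (70.2), Tmlhe, a hydroxylase of carnitine synthesis (64.9), and Prss35 (52.8).

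With both components required to hold at least 20% of the tumours, 62 genes were called and 0 of the simulated normal genes, and 74 without the 3 arrays, 49 of them shared. Here too, the simulation does not tell 2 levels from a skewed spread. Of the 62 genes, 17 lay on chromosome 4, against 3.72 expected from its number of tested genes. Genes of this chromosome change together, so they are not independent and no p value is given. The following genes were chosen after their values were seen. On chromosome 4 gaps ranged from 0.54 log2 (Txlna) to 0.95 (Slc35a1) apart from Lao1 at 3.66 and Gm8439 at 2.59, with Rnf20, a ubiquitin ligase of histone H2B, at 0.72 and Virma, of the RNA methylation complex, at 0.75. Elsewhere D730005E14Rik had a gap of 2.89 with 38% of the tumours in the upper component, D17H6S56E-5 one of 2.69 with 58%, and 2610507I01Rik one of 2.11 with 56%.

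**Figure D5:**
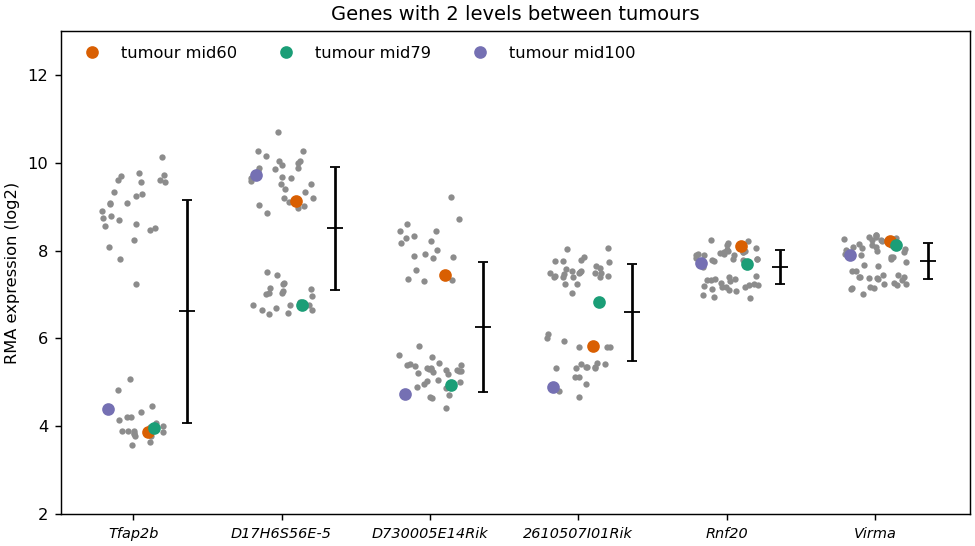
Levels (log2, vertical axis) of Tfap2b, D17H6S56E-5, D730005E14Rik, 2610507I01Rik, Rnf20 and Virma in the 50 tumours, 1 point per tumour, with bars for the mean and SD and colours for mid60, mid79 and mid100. The fitted components of Tfap2b are 4.92 apart (a lower bound, since low values are compressed), those of D730005E14Rik 2.89 and those of D17H6S56E-5 2.69. Rnf20 and Virma on chromosome 4 have gaps of 0.72 and 0.75.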

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

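The runs without mid60, mid79 and mid100, the arrays with mean correlation under 0.96, were chosen after the results were seen. In all 874 alternative values were computed. Of 92 for whole comparisons 64 stayed within their limits and 28 moved. Of those for named genes and correlations 681 kept their side of the threshold, 96 kept their direction but no longer passed, and 5 came to pass. Changes of direction in a value that passed before or after numbered 0. A change of sign between 2 values that did not pass was counted as kept, as for endothelium and hypoxia (r = -0.0222, rho = 0.118). Genes named from regressions had been selected to keep their sign without the 2 tumours, so the absence of reversals there was fixed in advance.

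Without the 2 tumours farthest from the predictor's median, 82 genes were associated with Erbb2 (5649 over all 50), 917 with proliferation (3414) and 513 with the T and NK cell score (5001). Without the 3 arrays these counts were 29, 1144 and 420, and the called lists 10 for Erbb2, 7 for proliferation and 13 for the T and NK cell score (18, 13 and 18 over all 50). Without the 2 tumours 12, 16 and 13 lists were called. Only the tumours differ in these runs, so the counts of single genes depend on few biopsies. Over all 50 tumours, limma gave as many genes in 0 of 100 shuffles of each predictor (highest 1578, 280 and 1015). With the predictor replaced by its ranks 868, 1313 and 1972 genes passed, and with array weights 783, 1397 and 916. With fibroblast, endothelium, adipocyte and macrophage scores as covariates the counts were 2053, 678 and 173 genes and 9, 7 and 9 lists. For ranks, weights and covariates the cause was not tested. With an estimated correlation in camera 1, 1 and 0 lists passed, the 0 for the T and NK cell score with 7 lists at an unadjusted p under 0.05, since that setting widens the error of lists whose genes move together.

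With the median absolute deviation 16 of 33 lists were more variable than matched genes (26 by SD), and by Spearman's rho 13 of 28 score pairs passed (20 by r). Both give single tumours less weight, but the cause was not tested. Genes with 2 levels numbered 658 at a BIC difference over 20 and 62 with each component at 20% or more, both stricter by construction, and 477 without the 3 arrays (1483 in all).

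The adjacent-gene mean r of 0.129 stayed between 0.116 by Spearman's rho and 0.162 above the 50th percentile, and each of its 5 alternatives exceeded all shuffles. The filters, the choice of probe set and another quantile normalization left every whole comparison within its limits. Weak signals limit low genes, and 50 tumours limit how well any relation that a few unusual biopsies carry can be measured.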

Other observations

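The tests of chromosomes 4, 12 and 18 and of the low Erbb2 in mid60 and mid79 were chosen only after their results were seen, as were, for genes with 2 levels, the test at any share without the 3 odd arrays and the demand for enough gene pairs outside chromosome 4. The genes and tumours named in this part were also chosen then. The biopsy mid60 had the highest skin score, 6.29. Against the median of 50 tumours, Sprr1a, of the cornified envelope, was higher by 7.15 log2, the keratins Krt14 and Krt10 by 5.83 and 5.24, and the Wnt pathway inhibitors Apcdd1 and Wif1 by 4.77 and 4.22. Krt6a was at 10.19 and Lgr5, a receptor of epithelial stem cells, at 6.63, where their medians, 3.83 and 4.02, lie under the filter at 4.09. Foxa1 was higher by 3.32 and Pgr, the progesterone receptor, by 2.55, while the deviation of Kit was -4.22 and that of Lalba, alpha-lactalbumin, -3.91. Its ligand genes Tgfa and Hbegf were higher by 1.38 and 1.21. Its neutrophil score, 3.82, was also the highest of the 50, with scores of 2.57 for B cells, 1.72 for macrophages and 1.63 for T and NK cells.

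In mid79, fat and lymphoid genes were high together. Retn, resistin, was higher by 6.79 log2, Lep by 6.67, Cd79a by 4.44 and Cldn5, of endothelial junctions, by 4.47, while the deviation of Cdh1 was -3.84, that of Epcam -2.90 and that of Mki67 -2.58. Adipoq was at 10.29 with its median, 4.05, under the filter. In mid100, the muscle gene Ttn was higher by 6.70 with Erbb2 at 11.43. Some 2-level genes followed a neighbour more closely than any gene on other chromosomes. D17H6S56E-5 correlated with Vars, the next gene, at r = 0.911, against 0.524 for the highest absolute r elsewhere, and D730005E14Rik with Apobec3, the next gene, at 0.775 against 0.486. Tfap2b did not, with 0.452 for Stau2 against 0.544 elsewhere.

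Low Erbb2 in mid60 and mid79 was weighed against other tissue in the biopsy. In mid79 the luminal list deviated by a median of -2.35 log2, close to the -2.46 of Erbb2, with adipocyte and B cell scores of 5.32 and 4.90, so fat and lymphoid tissue in place of tumour cells may account for its low Erbb2. In mid60 the median luminal deviation was 0.46, but its members went both ways, with Foxa1 up and Kit down, and other epithelia express some of them, so this value does not decide. Other tissue in place of tumour cells and a changed tumour cannot be told apart for mid60.

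Shared changes along chromosomes 4, 12 and 18 were weighed against cell composition, inherited segments and gain or loss of chromosomes. Without the 3 odd arrays and with 6 cell-type scores regressed out, at least 109% of the mean r of distant genes was kept on each, which argues against composition. Genes from opposite ends of a chromosome correlated at 0.0667 or more (SE 0.0157 on chromosome 12, the lowest). Inherited segments were predicted to give values near 0. That assumed that they raise about as many genes as they lower and that recombination parts the ends. Neither was tested, so this value does not decide. Chromosomes 5, 2 and 16, which were not picked, gave 0.0734, 0.0652 and 0.0638. At least 80.4% of the genes correlated positively with the rest of their chromosome, but these 3 chromosomes were picked because their genes correlate, and chromosome 7 had 81.4%. The shifts are medians over a chromosome's genes and were above 0.2 in 12, 7 and 5 tumours on chromosomes 4, 12 and 18. To give this, inherited alleles would have to raise most genes of a chromosome at once. These values therefore argue against inherited segments as the only cause. Gain or loss of whole chromosomes in part of the tumours stays an open hypothesis without DNA measurements. Regional bias such as probe GC content was not tested.

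Genes with 2 levels were weighed against inherited segments, probe mismatch and the odd arrays. Without mid60, mid79 and mid100, 477 genes were called against 1483 with them, while leaving out 3 other arrays, in 5 random choices, left 1367 to 1394, so those arrays may be the source of most calls. With both components at 20% or more, 74 genes were called without them against 62, but 3 arrays of 50 cannot make a component of that size, so this test decides nothing. Pairs within 50 genes had a median absolute r 0.447 above pairs on different chromosomes, but without chromosome 4 the difference was 0.187 over 12 pairs, between the limits of 0.05 and 0.2 set beforehand. Inherited segments therefore stay open for these pairs, and the other 12 lay on chromosome 4, where genes change together as described above. For probe mismatch with the FVB/NJ sequence as the only cause, 0% of the 15 strongly correlated pairs were negative (exact upper 95% limit 21.8%). Only 4 of those pairs lay outside chromosome 4, too few to decide. These 4 include Mir669j with Mir669k (r = 0.940) and Dcpp2 with Dcpp1 (r = 0.951), which have related symbols and need not be independent measurements. They are also among the 12 pairs outside chromosome 4 above. Inherited alleles possibly underlie single genes such as D17H6S56E-5, which the cross would allow, but genotypes were not used here.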
